A study of Sus scrofa with 57 samples.

How the data were processed

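Bulk RNA sequencing libraries were made from the prefrontal cortex of 57 pigs at 21 days of age. Per the labels' protocols, total RNA was isolated with TRIzol, purified on columns and turned into stranded mRNA libraries with a TruSeq kit for an Illumina sequencer. The protocol in the labels describes reads from one end of the fragments, while the series design text speaks of paired-end sequencing, and the deposited table does not settle which is right. The protocol also mentions a first and a later round of sequencing lanes, but no label ties a library to a lane, so no sequencing batch could be modelled. No label gives the dam or litter of a pig. Pigs of one litter share a dam and its infection, and p-values below treat every library as independent.

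The authors deposited 1 table of estimated counts per gene with 26687 rows and 57 columns, and 48.3% of its values are not whole numbers within a tolerance of 1e-09. Per the submitters' processing notes the reads were quantified with kallisto 0.43, a pseudoaligner that assigns reads to transcripts. The transcript set, the genome build and the step from transcripts to genes are not given in the sources used here, so no coordinates are printed. Of the rows, 26654 carry a symbol found in the gene table of the Sscrofa11.1 assembly, which was used only for names, and 9781 are uncharacterised loci. A further 31 rows are second rows of a symbol already present, and those symbols were not eligible for naming by size of change. Reads shared between close copies, such as the genes of the swine leukocyte antigen (SLA) complex, could have been divided between them by the quantification, so values of single SLA genes are uncertain.

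From there the estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 8 groups (minimum count 10), which left 20454 genes, and libraries were scaled by TMM, with factors from 0.932 to 1.1. A quasi-likelihood model with a mean for each of the 8 groups of maternal status, treatment and sex was fitted to all 57 libraries with robust dispersions. The common biological coefficient of variation was 0.268. Each comparison was a contrast of the 8 means with equal weights, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene in the text comes from this edgeR test unless another tool is named. The standard error (SE) of a log2 fold change is the fold change divided by the square root of the test's F value. Levels are CPM, counts scaled to a common library total after TMM scaling, given as mean ± SD.

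Of 41 gene lists written before the data were examined, 39 had at least 3 measured members. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. With the estimated correlation, the only call that held was that of X-linked genes escaping inactivation in the comparison of the sexes. The lists for cell adhesion molecules and for long-term depression follow pathways that the study itself reported on these samples and are not independent evidence. A list score per library is the mean over the list of log2 CPM (prior count 2) minus the mean of the 13 Control libraries.

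Genes named in the text were picked by a rule fixed before the data were examined. For morphine, maternal PRRS, sex and the morphine by maternal PRRS interaction these are the 8 higher and 8 lower genes with the largest fold change that passed the test, had a symbol, a mean of at least 1 CPM and the same direction in both sexes (for sex, in all 4 cells of maternal group and treatment). For other comparisons the 5 higher and 5 lower genes were taken. Up to 4 passing members per list were added, with OPRM1 in the treatment comparisons and the sex-linked genes used to check labels. Some genes that met the rule are not reported here.

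Alternatives fixed in advance were RLE size factors, no low-count filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma voom with sample quality weights, and 2 surrogate variables from sva 3.50.0. Further ones were an additive model, the compared groups alone, 1 random draw of 6 PRRS saline libraries per sex, and leaving out libraries. Depth ran from 28784087 to 50319309 counts per library. The fit was tested on simulated counts with 50 genes changed by each of the folds 1.5, 2, 4 and 8, among genes with a mean of at least 1 CPM. It recovered 90% of the 1.5-fold and 100% of the 2-fold changes for morphine (20275 genes tested), and 88% and 94% for maternal PRRS (20262 genes). For the morphine by maternal PRRS interaction it recovered 46% and 72% (20267 genes), and for PRRS within saline 76% and 98% (20248 genes). The simulation draws libraries independently and holds no shared structure such as litters. No 2 libraries were near-copies: over 1596 pairs the lowest chi-square per degree of freedom between counts was 14.4.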

Results

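The series measured gene expression in the prefrontal cortex of 21-day-old pigs, to ask how morphine and maternal immune activation act on this tissue. Dams were either controls or in the group labelled PRRS, the usual abbreviation of porcine reproductive and respiratory syndrome, a viral disease of pigs, and the offspring received morphine, an opioid, or saline. The Control pigs comprised 4 females and 2 males given saline and 3 females and 4 males given morphine. The PRRS pigs comprised 17 females and 15 males given saline and 6 females and 6 males given morphine. Library depth was 28784087 to 50319309 counts, and mean depth per maternal group and treatment lay between 36913798 and 39557536 counts. These means pool the sexes. Among the 8 groups of maternal status, treatment and sex, the 2 Control saline males had the lowest mean depth. The library with 28784087 counts was Control saline male replicate 13. The comparisons weight the sexes equally, and whether this difference in depth affected them was not tested.

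Sex-linked genes were examined first, because they check the labels. EIF1AY, the Y-linked copy of a translation initiation factor gene, had 0 to 6 counts in 29 of the 30 libraries labelled female and 708 to 1821 counts in 26 of the 27 labelled male. The library labelled PRRS morphine female replicate 19 had 761 counts, and the library labelled PRRS morphine male replicate 25 had 0. EIF2S3, an X-linked translation initiation factor that escapes X inactivation, was also nearer to the other sex in both: 44.8 CPM in the library labelled female replicate 19 and 65.2 CPM in the library labelled male replicate 25. The other females ranged from 68.8 to 85.3 CPM and the other males from 42.8 to 59.9 CPM, so replicate 25 lay between the 2 ranges for EIF2S3. Both libraries stayed in the fit under their labels, and the XIST transcript was not used here.

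**Figure D1:**
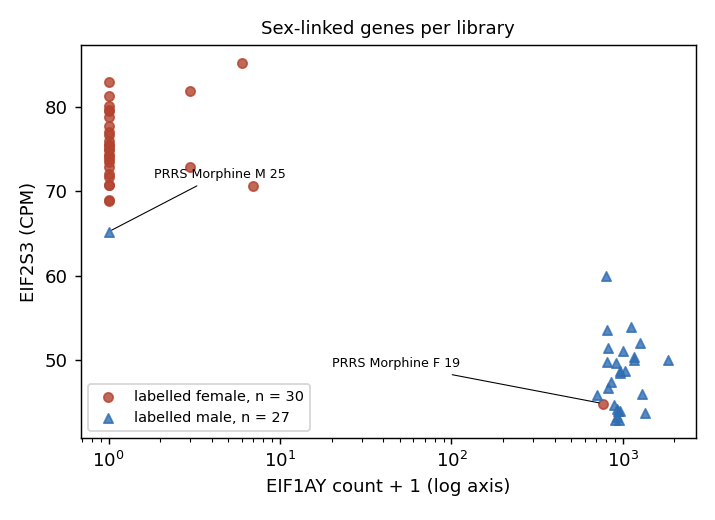
EIF1AY count plus 1 (log axis) against EIF2S3 in CPM for each of the 57 libraries, coloured by labelled sex. The 2 named libraries lie nearer to the opposite sex, at 761 and 0 EIF1AY counts.

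Between the sexes, 8 genes were higher in females and 14 were higher in males. X-linked genes that escape inactivation led in females: the transcription factor gene ZFX differed by 0.77 ± 0.09 on the log2 scale (SE, adjusted p = 1.09e-08). EIF2S3 differed by 0.60 ± 0.05 (adjusted p = 1.54e-11), the histone demethylase gene KDM6A by 0.47 ± 0.08 (adjusted p = 5.49e-04), and USP9X, TXLNG and SYAP1 by 0.38, 0.36 and 0.20. EIF1AY was lower in females by a log2 fold change of -8.89 ± 0.83, and the lipase gene CEL by -0.84 ± 0.19 (adjusted p = 0.0368). The EIF1AY value includes the 2 libraries that contradict their labels, at 761 counts under female and 0 under male. Of 9 measured X-escape genes 5 were higher in females, 7 when adjusted over the list alone, and the list was called with an estimated correlation too (adjusted p = 3.34e-10). Among autosomal lists, 21 of 22 oligodendrocyte markers had positive values (median 0.30, camera adjusted p = 4.98e-06), but no member passed and the adjusted p was 0.857 with an estimated correlation. That median was 0.63 without Control morphine male replicate 7 and 0.20 without Control saline male replicate 13.

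Genes of the interferon response and of immune cells were among those that differed between offspring of PRRS and Control dams. Averaged over treatment and sex, 45 genes were higher and 10 lower in PRRS pigs. Among characterised genes that passed with a mean of at least 1 CPM, the largest increases were in CXCL9 and CXCL10, chemokines induced by interferon that attract T cells, at log2 fold changes of 5.27 ± 1.24 and 4.77 ± 1.12 (SE, adjusted p = 0.0449 for both). RSAD2 (4.70 ± 1.01), OASL (4.56 ± 1.04) and MX2 (3.17 ± 0.67), antiviral proteins induced by interferon, rose as well, with the ubiquitin-like UBD (4.10 ± 0.85) and the T cell surface protein CD2 (3.27 ± 0.79). MX2 averaged 16.1 ± 17.4 CPM in PRRS saline pigs (SD, n = 32) and 7.16 ± 9.87 in PRRS morphine pigs (n = 12), against 1.44 ± 0.96 in Control saline pigs (n = 6) and 1.41 ± 0.93 in Control morphine pigs (n = 7).

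Of 34 interferon-response genes measured, all had positive values, 9 passed over all genes and 32 passed when adjusted over the list alone (median log2 fold change 1.62). PARP14 and HERC5, both induced by interferon, rose by 2.08 ± 0.45 and 2.58 ± 0.57 (adjusted p = 0.0449 for both). Of 25 antigen-presentation genes 7 rose, 23 when adjusted over the list alone. Among these were SLA-DRA, a class II antigen-presenting chain (3.67 ± 0.80), the peptide transporter TAP2 (1.19 ± 0.27), the class I transactivator NLRC5 (1.58 ± 0.36) and the immunoproteasome subunit PSMB9 (1.80 ± 0.42). Markers of T, NK and B cells had a median of 1.97, and 2 of 16 passed, CD2 and the T cell kinase LCK (2.98 ± 0.69), or 12 when adjusted over the list alone. Of 28 inflammatory cytokine genes 27 had positive values (median 0.96), 1 passed and 8 passed when adjusted over the list alone (camera adjusted p = 4.21e-06, adjusted p = 0.571 with an estimated correlation). Of 88 cell adhesion molecules, a list the study chose on these samples and so not independent evidence, 3 rose: SLA-DRA, SLA-DQA1 and CD2, which belong to antigen presentation and T cells. Camera called the interferon (adjusted p = 5.49e-30), antigen-presentation (7.17e-24) and T, NK and B cell lists (1.25e-08). None was called with an estimated correlation (adjusted p = 0.199, 0.199 and 0.29).

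**Figure D2:**
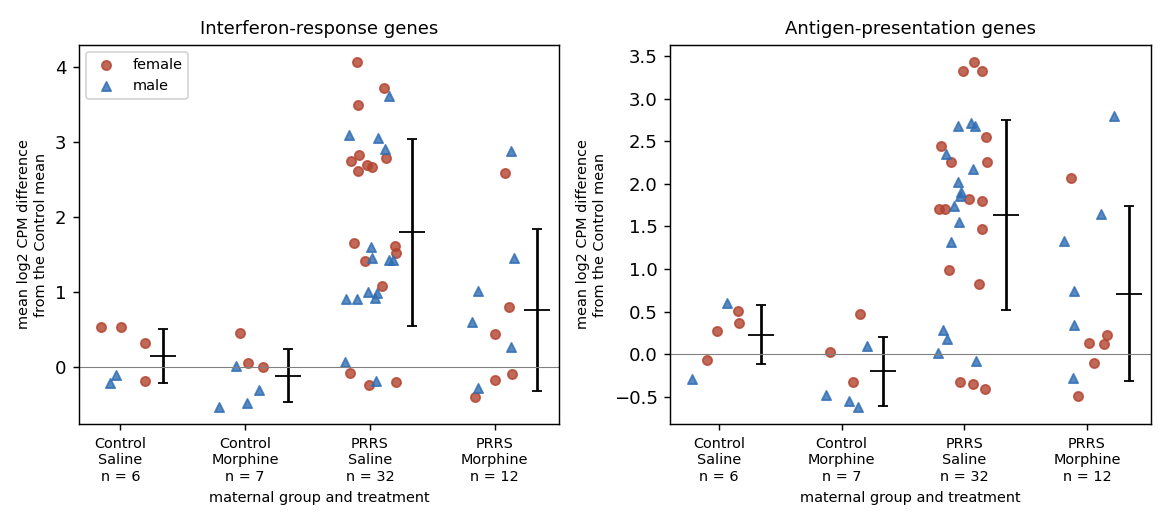
Mean log2 CPM of interferon-response genes (left) and antigen-presentation genes (right) per library, as the difference from the Control mean, with mean and SD beside each group. Of the PRRS libraries, 27 of 32 given saline and 6 of 12 given morphine lay above the highest Control library (0.53) for the interferon genes.

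The PRRS libraries varied widely in these genes. The interferon score ran from -0.24 to 4.07 in PRRS saline pigs and from -0.40 to 2.88 in PRRS morphine pigs, against -0.54 to 0.53 in all 13 Control pigs. Lower in PRRS pigs were LOX, a collagen crosslinking enzyme (-2.0 ± 0.36, adjusted p = 0.00666), and GLUL, the astrocyte enzyme glutamine synthetase (-0.61 ± 0.14, adjusted p = 0.0449). GLUL fell from 2500 ± 890 CPM in Control saline pigs to 1620 ± 503 CPM in PRRS saline pigs. The retinoid-binding CRABP2 (-1.93 ± 0.40) and the iodide transporter SLC5A5 (-1.49 ± 0.34) were lower too. CRABP2 reached 63.3 CPM in a single Control saline library and at most 2.50 CPM in PRRS saline pigs. Without that library, female replicate 10, CRABP2 was at -0.85 (adjusted p = 0.299) and SLC5A5 at -0.76 (0.333). SLC25A15, a mitochondrial ornithine transporter, and PGM1, phosphoglucomutase, differed by -0.23 ± 0.06 and -0.17 ± 0.04. Erythrocyte markers had a median of -0.45, which was -0.0492 (camera adjusted p = 0.0761) without Control morphine female replicate 2. All 19 measured nuclear oxidative-phosphorylation genes had negative values (median -0.14), of which 0 passed over all genes and 10 were lower when adjusted over the list alone (camera adjusted p = 5.43e-13, adjusted p = 0.29 with an estimated correlation). Between PRRS and Control pigs the score of this list differed by -0.317 with saline (permutation p = 0.00114, adjusted p = 0.0622 over 273 list tests). With morphine it differed by -0.00098 (p = 0.993). The morphine by maternal PRRS interaction of this score was 0.316 (permutation p = 0.0815, adjusted p = 0.342). Neither the difference with saline nor the interaction passed after adjustment. Meningeal markers had a median of -0.25, which was -0.03 without Control saline female replicate 10 (camera adjusted p = 5.28e-04 and 0.255, and adjusted p = 0.571 with an estimated correlation over all libraries). The count of 55 genes was 5 without the 2 libraries that contradict their sex labels. Leaving out 1 Control library at a time gave 45 without morphine male replicate 7, 43 without saline female replicate 9 and 1 to 27 without any other, the 1 without saline male replicate 13.

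Within saline-treated pigs, 591 genes were higher and 445 lower in PRRS than in Control offspring. CXCL10 (5.74 ± 1.73, adjusted p = 0.045), OASL (5.67 ± 1.65), RSAD2 (5.51 ± 1.56), UBD (4.66 ± 1.29) and CD2 (4.34 ± 1.22) had the largest increases among characterised genes that passed with a mean of at least 1 CPM. Of the 34 interferon-response genes 18 rose, 32 when adjusted over the list alone, with MX2 at 4.01 ± 1.04, PARP14 at 2.62 ± 0.69, CMPK2 at 1.54 ± 0.39 and EIF2AK2 at 1.34 ± 0.35. Of 25 antigen-presentation genes 9 rose, 23 when adjusted over the list alone, including TAP1 (1.80 ± 0.52) and SLA-3 (1.73 ± 0.49). T cell genes CD3G (3.56 ± 1.03) and GZMA (4.41 ± 1.29) rose, at low means of 0.574 and 0.246 CPM over all libraries. Of the microglial markers only CTSS (1.78 ± 0.54) and LY86 (2.95 ± 0.91) passed. The microglial score differed by 0.263 (permutation p = 0.344), and 11 of 32 PRRS saline libraries lay above the highest Control library in it.

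Genes of the respiratory chain were among the lower genes of the same comparison. All 19 measured nuclear oxidative-phosphorylation genes had negative values (median -0.32), 9 passed, and 19 passed when adjusted over the list alone. NDUFA1 (-0.34 ± 0.07), SDHB (-0.32 ± 0.08), NDUFA4 (-0.45 ± 0.11) and COX7A2 (-0.44 ± 0.11) were among them. Camera gave an adjusted p of 1.30e-14 for this list, the adjusted p was 0.487 with an estimated correlation, and fry gave 0.0113. The mean score of the oxidative-phosphorylation list was 0.19 ± 0.22 in Control saline (SD, n = 6) and -0.08 ± 0.18 in PRRS saline libraries (n = 32). The highest Control saline score of this list was 0.524, in male replicate 13. Without that library 0 genes were called in this comparison. All 42 ribosomal protein genes had negative values too (median -0.22), of which 0 passed (camera adjusted p = 4.18e-12, adjusted p = 0.559 with an estimated correlation). Astrocyte genes fell in 3 of 16 cases: the gap junction gene GJB6 (-0.83 ± 0.23), GLUL (-0.69 ± 0.20) and ALDOC (-0.29 ± 0.09). Of 58 long-term depression genes, a list the study chose on these samples and so not independent evidence, 6 rose, 10 when adjusted over the list alone. They included GUCY1A2 (0.60 ± 0.16), PLA2G4F (0.78 ± 0.23) and GNAQ (0.47 ± 0.14). PPP1R1B, a gene of the dopamine list that encodes the phosphoprotein DARPP-32, fell (-0.64 ± 0.17). It is also on the list of markers of the striatum, a neighbouring brain region. Control saline male replicate 13, without which 0 genes were called, had the highest dopamine (0.587) and striatum (0.514) scores of the 6 Control saline libraries. The opioid precursor gene POMC (-0.54 ± 0.14) and the neuropeptide gene GAL (-1.37 ± 0.40) were lower. The AMPA receptor gene GRIA2 (0.54 ± 0.17), the clock gene CLOCK (0.68 ± 0.20) and the adhesion gene CDH2 (0.42 ± 0.09) were higher. POMC, GAL, GRIA2 and CLOCK were each the only passing gene of the opioid, neuropeptide, glutamate receptor and clock lists. In that order, the list scores differed by 0.00505, -0.218, 0.116 and 0.0893 (permutation p = 0.951, 0.053, 0.119 and 0.116).

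**Figure D3:**
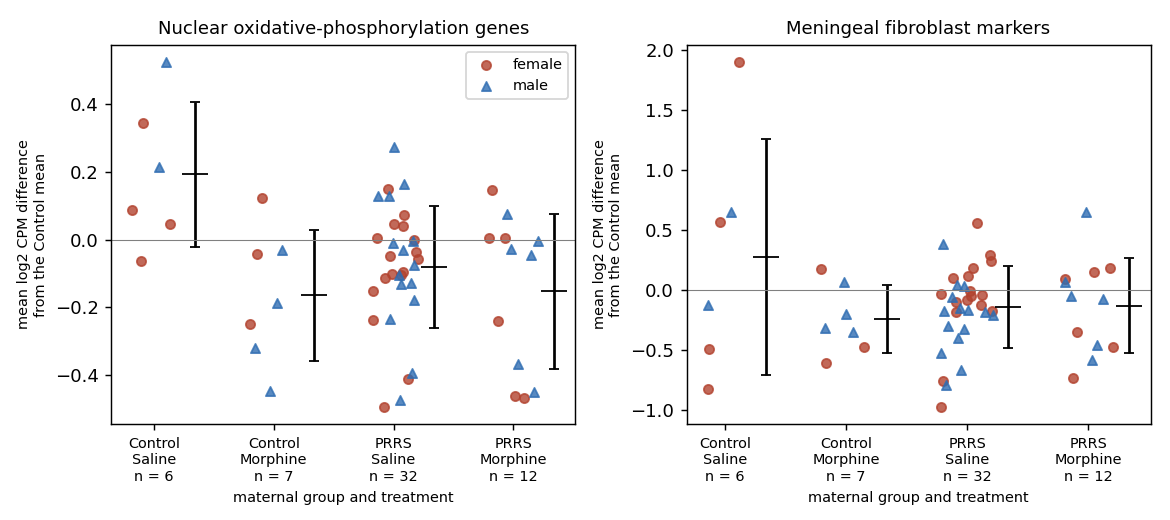
Mean log2 CPM of nuclear oxidative-phosphorylation genes (left) and meningeal fibroblast markers (right) per library, as the difference from the Control mean, with mean and SD beside each group. Control saline libraries average 0.19 on the left, and 1 of them reaches 1.90 on the right.

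Markers of the meninges, the membranes around the brain, also fell within saline-treated pigs: 5 of 16 passed, 8 when adjusted over the list alone (median -0.65). IGFBP2 (-0.95 ± 0.19), SLC13A4 (-1.73 ± 0.34), FMOD (-1.06 ± 0.22) and SLC22A6 (-0.86 ± 0.20) were lower, with camera adjusted p = 2.79e-06 and 0.501 with an estimated correlation. Among characterised genes that passed with a mean of at least 1 CPM the largest decreases were in CRABP2 (-3.48 ± 0.47, adjusted p = 1.2e-05), SLC22A8 (-3.15 ± 0.51), SLC5A5 (-3.05 ± 0.41), C3H16orf89 (-2.86 ± 0.53) and CRABP1 (-2.43 ± 0.45). Most of these calls rest on Control saline female replicate 10, whose meningeal score was 1.90. Without it the median of the meningeal markers was -0.21 (camera adjusted p = 0.0392). C3H16orf89 was at -0.20 (adjusted p = 0.814), SLC13A4 at -0.37 (0.403), SLC22A6 at -0.42 (0.136), SLC22A8 at -0.73 (0.0955), FMOD at -0.65 (0.0661), CRABP2 at -1.33 (0.062) and CRABP1 at -1.60 (0.0537). IGFBP2 (-0.66, adjusted p = 0.0494) and SLC5A5 (-1.60, adjusted p = 0.0449) stayed past the threshold. Of 13 choroid plexus markers 8 had negative values (median -0.27) and 2 passed, SLC5A5 and the transthyretin gene TTR (-1.92 ± 0.60, adjusted p = 0.0495), which was at -2.01 (0.0602) without Control saline female replicate 10. That list had an adjusted p of 0.0601 by camera, 0.501 with an estimated correlation and 0.0487 by fry. The count of 1036 genes became 280 without Control saline female replicate 10, 87 without Control saline female replicate 11, 591 without male replicate 12 and 0 without male replicate 13. With PRRS saline groups thinned to 6 libraries per sex, in 1 random draw, it was 0.

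Within morphine-treated pigs, edgeR called 0 genes between PRRS and Control offspring. At an unadjusted p under 0.05 there were 485 genes, where 1023 would be expected by chance, and DESeq2 called 13 and limma voom 1. All 34 interferon-response genes had positive values (median 1.12, camera adjusted p = 2.06e-20, adjusted p = 0.404 with an estimated correlation). All 25 antigen-presentation genes did as well (median 1.08), and 9 passed when adjusted over the list alone. OPRM1, the mu opioid receptor to which morphine binds, differed by -0.31 ± 0.31 (adjusted p = 1).

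Morphine, averaged over maternal group and sex, was accompanied by 37 higher and 30 lower genes. TMEM253 (0.53 ± 0.12, adjusted p = 0.0444), N4BP2 (0.47 ± 0.11), the chromatin gene BAZ2B (0.44 ± 0.11), FSBP (0.44 ± 0.10), the chromosome maintenance gene SMC5 (0.37 ± 0.08), PHF21B (0.36 ± 0.09), USP45 (0.35 ± 0.09) and the activin receptor gene ACVR2B (0.35 ± 0.09) were higher. The lower genes included CDC20, an activator of the anaphase-promoting complex (-0.81 ± 0.17, adjusted p = 0.0374), the cyclin CCNB1 (-0.74 ± 0.17), CKS2 (-0.64 ± 0.15), the mitotic kinase AURKA (-0.39 ± 0.08) and the spindle protein TPX2 (-0.31 ± 0.07). CDC20 stood at 1.58 ± 0.52 CPM in Control morphine pigs and 1.76 ± 0.56 in PRRS morphine pigs, against 3.17 ± 1.12 and 2.59 ± 0.92 with saline. LGALS1 (-0.62 ± 0.13), AVPI1 (-0.50 ± 0.11) and COX6B (-0.39 ± 0.09), a subunit of cytochrome oxidase, fell as well.

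Of 21 proliferation genes, 20 had negative values under morphine and 3 fell, 6 when adjusted over the list alone (camera adjusted p = 6.52e-08, adjusted p = 0.84 with an estimated correlation). All 19 oxidative-phosphorylation genes were negative (median -0.22). Of these NDUFV2 fell (-0.20 ± 0.05), and 19 fell when adjusted over the list alone, with camera adjusted p = 1.06e-14, 0.84 with an estimated correlation and 0.0272 by fry. The mean score of this list was highest in Control saline libraries, at 0.192. The other means were -0.165 in Control morphine, -0.0813 in PRRS saline and -0.152 in PRRS morphine libraries. Single libraries overlapped: Control saline scores ran from -0.0633 to 0.524 and PRRS saline scores from -0.494 to 0.272. Within PRRS pigs the score differed by -0.0714 with morphine (permutation p = 0.289). All 25 antigen-presentation genes had negative values (median -0.68), but 0 passed, and the adjusted p was 0.84 with an estimated correlation. OPRM1 differed by 0.60 ± 0.24 (adjusted p = 0.121) at low levels, 0.244 ± 0.155 CPM in Control saline and 0.579 ± 0.423 CPM in Control morphine pigs. SLC22A8, an organic anion transporter, was lower as well (-1.64 ± 0.39), which became -0.43 (adjusted p = 0.179) without Control saline female replicate 10. Of 16 meningeal markers 14 had negative values (median -0.43), 0 passed over all genes and 9 were lower when adjusted over the list alone (camera adjusted p = 0.00461, adjusted p = 0.84 with an estimated correlation). Without that library their median was -0.215 (camera adjusted p = 0.236). The count of 67 genes became 0 without the 2 libraries that contradict their sex labels, and ranged from 0 to 1402 when each Control library was left out.

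Within Control pigs, 24 genes were higher and 2 lower with morphine. N4BP2 (0.84 ± 0.19), the Mediator subunit gene MED13L (0.70 ± 0.15), SMC5 (0.60 ± 0.14), the polyadenylation factor gene CPSF6 (0.59 ± 0.14) and OTUD6B (0.56 ± 0.12) were higher, with adjusted p values of 0.0498 or 0.05 after rounding. FAM118B was lower (-0.34 ± 0.08), as was SLC22A8 (-3.31 ± 0.67), at -0.88 without Control saline female replicate 10. All 19 oxidative-phosphorylation genes had negative values, and 19 passed when adjusted over the list alone (median -0.38, camera adjusted p = 4.93e-15, adjusted p = 0.485 with an estimated correlation). Meningeal markers had a median of -0.84, with 0 of 16 lower over all genes and 9 lower when adjusted over the list alone (camera adjusted p = 1.64e-04, adjusted p = 0.883 with an estimated correlation). Without Control saline female replicate 10 that median was -0.43 (camera adjusted p = 0.115). OPRM1 differed by 1.27 ± 0.42 (adjusted p = 0.0781). The count of 26 became 4 with RLE scaling (3 higher and 1 lower) and 0 with the Control groups fitted alone. Leaving out each Control library gave 25 without morphine male replicate 5 and otherwise counts from 0 to 1873, the highest without morphine male replicate 4.

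Within PRRS pigs, 13 genes were higher and 3 lower with morphine. PHF21B rose by 0.47 ± 0.09 (adjusted p = 0.00348), from 11.5 ± 1.83 CPM with saline (SD, n = 32) to 15.9 ± 2.92 CPM with morphine (n = 12), and GCDH, a mitochondrial dehydrogenase, by 0.24 ± 0.05. FAM72A (-0.50 ± 0.10), the autophagy receptor gene OPTN (-0.34 ± 0.07) and the kinase gene MAP2K6 (-0.22 ± 0.05) fell. EIF1AY was called at 3.89 ± 0.63, but its value was -0.97 (adjusted p = 0.476) without the libraries labelled female replicate 19 and male replicate 25. Without these libraries 3 of the 16 genes were called, PHF21B (0.50) and OPTN (-0.42) among them. All 34 interferon-response genes had negative values (median -0.96), 0 passed over all genes and 30 passed when adjusted over the list alone. Camera gave this list an adjusted p of 4.00e-23, and the adjusted p was 0.276 with an estimated correlation. T, NK and B cell markers had negative values in 15 of 16 cases (median -1.35), antigen-presentation genes in 25 of 25 (-0.97), inflammatory cytokines in 25 of 28 (-0.94) and proliferation genes in 19 of 21 (-0.39). In these 4 lists 0 genes passed over all genes, and 11, 17, 14 and 16 passed when adjusted over the list alone. Their camera adjusted p values were 1.49e-05, 5.00e-17, 1.85e-04 and 1.62e-12, and 0.536, 0.276, 0.654 and 0.276 with an estimated correlation. The 16 astrocyte markers were all positive (median 0.24), of which 3 passed when adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). OPRM1 differed by -0.07 ± 0.22 (adjusted p = 0.937).

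**Figure D4:**
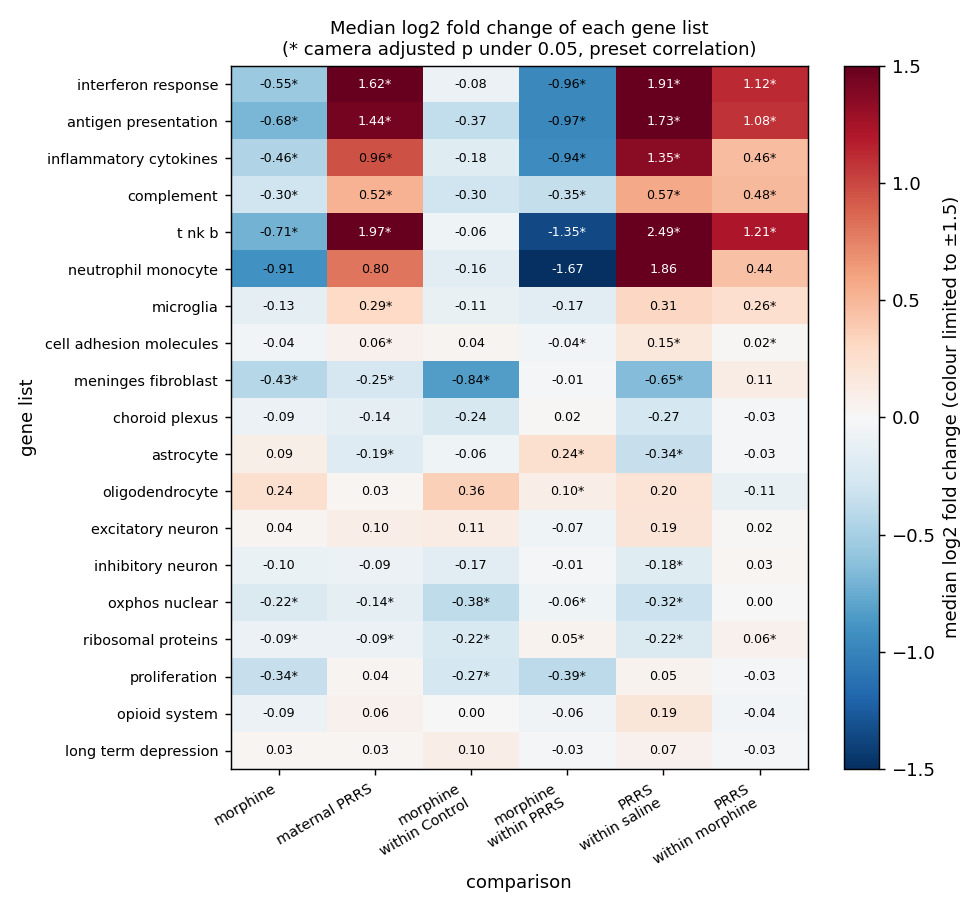
Median log2 fold change of 19 gene lists in 6 comparisons, with a star where camera at its preset correlation gave an adjusted p under 0.05. No star held with an estimated correlation; interferon-response genes have medians of 1.62 for maternal PRRS and -0.96 for morphine within PRRS.

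Whether morphine acted differently in PRRS and Control offspring was tested by the interaction, in which edgeR called 0 of 20454 genes. The smallest adjusted p was 0.146, for LIN7C, named after its value was seen. At an unadjusted p under 0.05 there were 3416 genes, and DESeq2 called 2 and limma voom 1. Meningeal markers (median 0.87), oxidative-phosphorylation genes (0.30) and ribosomal protein genes (0.28) had positive interaction values, and all 34 interferon-response genes negative ones (-0.97). None of these lists was called with an estimated correlation (adjusted p = 0.705, 0.705, 0.705 and 0.88). Without Control saline female replicate 10 the meningeal median was 0.41 (camera adjusted p = 0.0279). OPRM1 had an interaction of -1.34 ± 0.48 (adjusted p = 0.202).

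The interactions with sex gave 0 genes by edgeR as well. For morphine by sex 797 genes had an unadjusted p under 0.05, DESeq2 called 1 gene and limma voom 2, and OPRM1 stood at -1.23 ± 0.48 (adjusted p = 0.906). For maternal PRRS by sex there were 389 genes, with 1 by DESeq2 and 0 by limma voom. For the interaction of morphine, maternal PRRS and sex there were 1745 genes, with 2 by DESeq2 and 0 by limma voom, and OPRM1 at 2.28 ± 0.96 (adjusted p = 0.578).

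Pigs with both exposures differed from pigs with neither in 10 higher and 8 lower genes. CRABP2 (-3.46 ± 0.61, adjusted p = 0.0121), SLC22A8 (-3.12 ± 0.58), C3H16orf89 (-3.12 ± 0.65), SLC5A5 (-2.42 ± 0.52) and TNMD (-2.21 ± 0.47) were lower, and FMOD, a meningeal marker, fell by 1.23 on the log2 scale. NDUFA1 (-0.40 ± 0.08) and NDUFV2 (-0.32 ± 0.07) of the respiratory chain fell, and all 19 genes of that list passed when adjusted over the list alone (camera adjusted p = 2.63e-20, adjusted p = 0.344 with an estimated correlation). Camera called 5 lists downward and 1 upward here, and 0 with an estimated correlation. The interferon score averaged 0.754 ± 1.08 in PRRS morphine libraries (SD, n = 12) and 0.14 ± 0.359 in Control saline libraries (n = 6). OPRM1 differed by 0.96 ± 0.39 (adjusted p = 0.155). Without Control saline female replicate 10, CRABP2 was at -1.31 (adjusted p = 0.124), SLC22A8 at -0.69 (0.185), C3H16orf89 at -0.46 (0.627), SLC5A5 at -0.97 (0.211), TNMD at -0.78 (0.225) and FMOD at -0.82 (0.0898). The count of 18 became 3 without that library, 0 without Control saline male replicate 13, and 0 without the 2 libraries that contradict their sex labels.

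A pair of libraries stood apart from the rest in their correlation with other libraries. PRRS saline male replicate 44 had a median Spearman correlation of 0.9499 and PRRS saline female replicate 32 of 0.9688, against a median of 0.9852 over all libraries. Replicate 44 had a neutrophil and monocyte score of 6.42 and an inflammatory cytokine score of 5.24, each the highest of the 32 PRRS saline libraries. Without both libraries the maternal PRRS comparison had 94 genes in place of 55.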

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

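The tests of single Control saline libraries, blood, outlying libraries, T, NK and B cells, sex labels and the effect of morphine on the interferon score, and all permutation tests of scores, were chosen only after the result was seen. The splits and the tests with the meningeal and oxidative-phosphorylation scores were chosen before. Labels were redrawn within the other factors, 100 splits per comparison with the real one included. The splits take pigs as independent although litters are unknown, and their shares were not adjusted over the 12 comparisons.

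The first pattern is the 591 higher and 445 lower genes in PRRS against Control pigs given saline. Of 100 splits, 2 gave as many genes, with 1901 the highest of the others. That share was not adjusted over the comparisons, so chance is not excluded, even for pigs taken as independent. A split of 1901 genes may point to a structure of the samples that the labels do not give, which was not tested. With the meningeal score as a covariate the median log2 fold change had 85.3% of its size for the higher genes (0.43 to 0.36, median SE 0.117 before and after). For the lower genes it had 70.5% (-0.41 to -0.29). This argues only weakly against meningeal tissue as the whole cause, because the genes were picked in this same comparison. With that covariate 0 genes were called, as the values were smaller with errors of similar size. Without any single Control saline library the medians had at least 79.2% and 85.4% of their size. The genes were picked with all of these libraries in the fit, so this does not exclude that single libraries carried the calls. Without male replicate 13 the median SE rose from 0.117 to 0.146 and 0 genes were called. With the oxidative-phosphorylation score as a covariate 44.8% (0.43 to 0.19) and 41.7% (-0.41 to -0.17) remained and 10 genes were called, which is consistent with a difference in RNA or library quality and equally with a biological change in these genes, because that score is itself an outcome, while maternal PRRS and litter stay open and untested.

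The second pattern is the interferon signal of PRRS pigs given saline, whose score was higher by 1.72 ± 0.51 (SE) on the log2 scale, with a permutation p of 0.00224 and an adjusted p of 0.0836 over 273 list tests, which did not pass. The erythrocyte score showed no rise in PRRS pigs, with a difference of -0.526 ± 0.374 (permutation p = 0.176). Blood left in the tissue stays open, because that difference is not beyond its spread and red cell genes do not measure white blood cells. A few outlying libraries as the cause are argued against by the 27 of 32 libraries above the highest Control library. Of these 27, 5 had a T, NK and B cell score no higher than the highest Control library, which argues only weakly against transcripts brought in by those cells, since 5 just meets the bound used and the bound was chosen after the scores were seen. Interferon scores of PRRS pigs may be lower with morphine, but the permutation test of that difference (-1.03, p = 0.0161) had an adjusted p of 0.185 over 273 list tests and did not pass. Infection of the pigs themselves and unequal litters across the groups stay open and untested.

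The third pattern is the pair of libraries whose sex-linked genes contradict the label. Mixed RNA is argued against, because EIF1AY lay inside the range of the other sex in 2 of 2 libraries. EIF2S3 of replicate 25, at 65.2 CPM, lay between the ranges of the other females and other males, while its EIF1AY count was 0. All 6 values compared (EIF1AY, EIF2S3 and the X-escape score in each) lay nearer to the median of the other sex, as exchanged or wrong sex labels would give. They are not 6 independent checks, because EIF1AY picked the libraries and EIF2S3 belongs to the X-escape list. Whether the pigs' treatments were exchanged as well cannot be read from these genes, and both libraries carry the same maternal group and treatment.

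For the other counts, splits with as many genes as the real one were 5 of 100 for morphine (67 genes, highest other 898) and 13 for maternal PRRS (55, highest other 564). They were 6 for morphine within Control (26, highest other 2498) and 30 for morphine within PRRS (16, highest other 451), so chance is not excluded for these 4 counts. Chance is excluded for sex, where only the real labels gave as many (1 of 100 splits, 22 genes, highest other 9) and EIF2S3 had an edgeR adjusted p of 1.54e-11. For both exposures against neither (3 of 100, 18 genes, highest other 215) chance is not excluded, even for pigs taken as independent. That share was not adjusted over the comparisons. For the comparisons with 0 genes all 100 splits gave as many, with highest other counts of 3187 for morphine by maternal PRRS, 1592 for morphine by sex, 209 for maternal PRRS by sex, 521 for all 3 factors and 465 for PRRS within morphine. Other splits with many times the real count may point to a structure of the samples or to genes that vary together, and neither was tested.

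Of 160 list scores and depths examined in the 4 groups of 4 to 10 libraries, 10 had a library far from the others. Chance alone gives about 1 in 20, so 10 of 160 is close to that share. The library labelled PRRS morphine female replicate 19 stood out in antigen presentation (2.07, others up to 0.23), inflammatory cytokines (1.59), complement (1.25), T, NK and B cells (1.98), neutrophils and monocytes (1.85) and cholesterol synthesis (-1.09). That library contradicts its sex label and was compared with the others labelled female. PRRS morphine male replicate 20 stood out in heat shock genes (0.35). Control morphine male replicate 4 stood out in glucocorticoid response (0.67), Control morphine male replicate 7 in olfactory neuroblast markers (-0.28) and Control saline female replicate 11 in long-term depression genes (-0.13).

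Camera at its preset correlation called 36 differences of effects between groups, none of them with an estimated correlation. Ranges in brackets are those with each Control library left out in turn, a test chosen after the data were seen. In that test 28 of these 36 medians moved by more than 1.5 times or changed sign, and 26 lost or reversed their call at least once. For morphine by maternal PRRS the medians were 0.25 for dopamine genes (0.20 to 0.33), -0.97 for interferon response (-1.02 to -0.89), 0.26 for astrocytes (0.16 to 0.34), 0.175 for inhibitory neurons (0.0479 to 0.32) and 0.17 for endothelium (0.0609 to 0.30). The others there were 0.23 for mural cells (0.12 to 0.42), 0.87 for meninges (0.41 to 1.00), 0.28 for neuropeptides (0.15 to 0.40), 0.30 for oxidative phosphorylation (0.235 to 0.40) and 0.28 for ribosomal proteins (0.20 to 0.37). For morphine by sex they were 0.24 for immediate early genes (0.13 to 0.36), 0.18 for astrocytes (0.0815 to 0.31), 0.20 for inhibitory neurons (0.088 to 0.30), 0.17 for endothelium (0.02 to 0.28) and 0.15 for olfactory neuroblasts (0.0637 to 0.20). The others there were 0.28 for neuropeptides (0.115 to 0.36), 0.22 for oxidative phosphorylation (0.15 to 0.30), 0.15 for ribosomal proteins (0.0595 to 0.22) and -0.12 for X-escape genes (-0.19 to -0.059). For maternal PRRS by sex they were 0.16 for immediate early genes (0.0439 to 0.28), -0.32 for interferon response (-0.44 to -0.25), -0.50 for antigen presentation (-0.66 to -0.41), 0.20 for astrocytes (0.10 to 0.32) and -0.23 for oligodendrocytes (-0.95 to -0.0188). The others there were 0.185 for endothelium (0.0735 to 0.36), 0.25 for mural cells (0.0514 to 0.45), 0.0689 for ribosomal proteins (-0.0174 to 0.15) and -0.0882 for cholesterol synthesis (-0.26 to -0.00217). For all 3 factors they were -0.92 for interferon response (-1.06 to -0.76), -1.44 for antigen presentation (-1.68 to -0.97), -0.56 for microglia (-0.85 to -0.31) and -0.41 for astrocytes (-0.65 to -0.28). The others there were -0.44 for endothelium (-0.65 to -0.0394), -0.52 for proliferation (-0.75 to -0.29), -0.46 for oxidative phosphorylation (-0.60 to -0.305) and -0.40 for ribosomal proteins (-0.55 to -0.24).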

How the results depend on the processing

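Leaving out the 2 libraries that stand apart together with the 2 that contradict their sex labels, and the list tests without each Control library, were chosen only after the data were seen. The count of 22 for sex stayed within 1.5 times except with limma voom (36) and the additive model (52). The other counts moved strongly, and the cause was not tested unless given. With RLE scaling, morphine within Control had 4 genes. Without a low-count filter more genes are tested, and morphine had 12, maternal PRRS 8, morphine within Control 0 and PRRS within saline 519. At a mean of 1 CPM fewer are tested, and morphine had 443 and morphine within Control 333. DESeq2 called 707 for morphine, 273 for maternal PRRS, 533 for morphine within Control, 33 for morphine within PRRS, 1730 for PRRS within saline, 13 for PRRS within morphine and 163 for both exposures against neither. It called 2, 1, 1 and 2 for the interactions of morphine with maternal PRRS, morphine with sex, maternal PRRS with sex, and all 3 factors. Limma voom called 1394 for morphine, 26 for maternal PRRS, 187 for morphine within Control, 168 for morphine within PRRS, 1 for PRRS within morphine, 302 for both against neither, and 1 and 2 for the interactions of morphine with maternal PRRS and with sex. With 2 surrogate variables, morphine, morphine within Control and both against neither had 0, maternal PRRS 1, PRRS within saline 5 and morphine within PRRS 31. Without the libraries that stand apart, maternal PRRS had 94 and morphine within Control 0. Without those that contradict their sex labels, morphine and both against neither had 0, maternal PRRS 5, morphine within Control 182, morphine within PRRS 3, and PRRS within morphine and the interaction of all 3 factors 1 each. Without all 4 libraries, morphine had 1, maternal PRRS 4, morphine within Control 134, morphine within PRRS 3, both against neither 0, and PRRS within morphine and the interaction of all 3 factors 1 each. The additive model gave 30 for morphine and 187 for maternal PRRS. Fitted on the compared groups alone, morphine within Control and both against neither had 0. With 1 random draw of 6 PRRS saline libraries per sex, maternal PRRS had 186 and PRRS within saline 0. EIF1AY for morphine within PRRS reversed from 3.89 to -0.26 with limma voom, -0.97 without the libraries that contradict their sex labels and -0.43 without all 4, where the libraries that carried the difference are gone; for limma voom the cause was not tested. Leaving out each of the 13 Control libraries gave ranges of 0 to 1402 for morphine, 1 to 45 for maternal PRRS, 19 to 24 for sex, 0 to 1873 for morphine within Control, 13 to 22 for morphine within PRRS, 0 to 1466 for PRRS within saline and 0 to 191 for both against neither. The interaction of morphine with maternal PRRS had 0 to 2, and the other interactions and PRRS within morphine had 0 to 0. For PRRS within saline, counts outside 1.5 times of 1036 came without Control saline female replicates 10 (280) and 11 (87) and male replicates 12 (591) and 13 (0). For morphine, libraries beyond 1.5 times in Control morphine were female replicates 1 (131), 2 (0) and 3 (926) and male replicates 4 (1402), 5 (0), 6 (17) and 7 (3). In Control saline they were female replicates 8 (10), 9 (175), 10 (521) and 11 (4) and male replicates 12 (518) and 13 (0). Of the 117 list calls, camera with an estimated correlation kept 1 and fry 8. Leaving out each Control library gave 1370 list results on the same side of the threshold, 147 weaker and 4 of the other camera direction. These 4 medians were the lowest of their ranges. For ribosomal proteins in maternal PRRS by sex the range was -0.0174 (without Control saline male replicate 13) to 0.152. In PRRS within morphine the ranges were -0.00408 to 0.224 for endothelium and 9.53e-04 to 0.107 for ribosomal proteins (lowest without Control morphine female replicate 1), and -0.0239 to 0.169 for neuropeptides (lowest without Control morphine male replicate 7). For maternal PRRS, counts within 1.5 times of 55 came only without Control morphine male replicate 7 (45) and Control saline female replicate 9 (43). For morphine within Control only the count without Control morphine male replicate 5 (25) did. For both against neither, counts beyond 1.5 times of 18 came without Control morphine male replicates 4 (37) and 7 (61), and without Control saline female replicates 8 (37), 9 (63) and 10 (3) and male replicates 12 (191) and 13 (0). Depth limits genes with few counts: in the smallest library, of 28784087 counts, 0.1 CPM is under 3 counts. No paired analysis was possible because no replicate number occurs in more than 1 group.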

Other observations

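All 18 complement genes had positive values for maternal PRRS, and 0 passed over all genes (median 0.52, camera adjusted p = 4.21e-06, adjusted p = 0.524 with an estimated correlation), while 5 passed when adjusted over the list alone. Markers of oligodendrocyte precursors had positive values in 12 of 12 cases within PRRS pigs given morphine (median 0.22), of which 3 passed when adjusted over the list alone (camera adjusted p = 7.51e-06, adjusted p = 0.423 with an estimated correlation). Ribosomal protein genes had negative values in 42 of 42 cases for maternal PRRS (median -0.09) and for morphine (median -0.09), and 0 passed in either. Without Control saline male replicate 13 these medians were -0.0488 and -0.0408. The list tests without single Control libraries were chosen after the data were seen.

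Morphine within Control and PRRS within saline are both measured against the same 6 Control saline libraries. Of the 24 genes higher with morphine in Control pigs, 21 were among the 591 higher with PRRS in saline pigs, where independent lists would share 0.693, and 2 of 2 lower genes were shared. Across 20454 genes, which are not independent replicates, fold changes of these comparisons correlated at 0.608, while unchanged groups simulated against shared controls gave 0.704. The covariance was 0.0737 against 0.0475 simulated, and with the 6 controls divided between the comparisons in 12 ways the correlation averaged 0.229 and the covariance 0.0355. The simulated values leave out real effects and the independent overlap leaves out the shared controls.

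Scores of 39 lists were also compared in 7 contrasts by permutation tests with 100000 resamples, two-sided and chosen only after the data were seen. Of 273 tests, 0 had an adjusted p under 0.05. The lowest adjusted p, 0.0505, was shared by maternal PRRS on the interferon score (difference 1.28, p = 0.00035), the antigen-presentation score (1.15, p = 0.00042) and the cell adhesion score (0.32, p = 0.00074), and by PRRS within saline on the long-term depression score (0.11, p = 0.00069). The last 2 lists were chosen by the study on these samples and are not independent evidence.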
